A study of Danio rerio with 6 samples.

How the data were processed

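The series holds 6 libraries of poly(A) RNA from heads of zebrafish embryos at 2 dpf, 3 from embryos exposed to 500 µg/L 6PPD from 10 hpf and 3 from embryos in DMSO, each made from 150 pooled heads. Per the labels' protocols, embryos were kept at 28 °C, PTU (0.003%) was added from 24 hpf, RNA was extracted with TRIzol, and libraries were made strand-specific by the dUTP method from 1 µg of RNA with 8 PCR cycles and sequenced as paired 150 bp reads. The samples were grouped by the treatment named in their labels, and the replicate numbers come from their titles. The labels call the replicates biological.

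The deposited table gives FPKM, that is fragments scaled by gene length and by mapped fragments of the library, which the authors computed from their alignments. The submitters' processing notes name fastp, HISAT2, featureCounts, StringTie and the genome build GRCz11, without versions, roles or order. Whether strand was used in counting is not given in the sources used here. FPKM times gene length summed to 0.992×10⁶ to 1.04×10⁶ per library, and the FPKM themselves summed to 434258 (DMSO replicate 3) to 472121 (DMSO replicate 1), so the values are not rescaled to a common sum. Values of low genes were searched for steps of 1 fragment. Within a tolerance of 0.1 step, 23.3% to 25.7% of values up to 20.5 steps were whole multiples, where a step of arbitrary size gives 20%, so fragment counts were not recovered and no count model was used. A depth was read from the commonest low value in a preset window, which bounds the result, and is not established. It was 14.9, 15.6, 16.5×10⁶ units in DMSO replicates 1 to 3 and 14.3, 16.4, 15×10⁶ in 6PPD replicates 1 to 3. The 10 highest genes took 7.91% to 8.96% of the summed FPKM in each library.

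Gene symbols, positions and lengths were taken from the deposited table (32057 genes), with positions on GRCz11 as that table gives them. Genes with a mean of at least 1 FPKM over the 6 libraries (15320) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (empirical Bayes with an intensity trend, prior degrees of freedom 5.56, residual degrees of freedom 4), 6PPD against DMSO without further terms. The Benjamini-Hochberg adjusted p had to be under 0.05. All log2 fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. Values are given as mean ± SD of 3 libraries, and log2 fold changes with the moderated SE where one is printed.

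The 39 gene lists, written by hand from general knowledge before the data were examined, hold 1823 entries, of which 1753 matched a symbol in the table. They were tested with limma's camera (preset correlation 0.01, lists with at least 5 tested members), with camera under an estimated correlation, and with fry, each with Benjamini-Hochberg adjustment over the lists. Camera asks whether a list moved relative to all other tested genes, and fry whether its members moved on balance in one direction. Calls by fry refer to this directional test, and its mixed test asks for changes in either direction. The result of 1 list and of some single genes is not reported here. The lists share members, such as ptgs2a, cebpb, blvrb and gapdh. They cover ferroptosis, iron, oxidant defence, xenobiotic metabolism, vessel and barrier genes, cell types of the head and of neighbouring tissues, stress responses, cell cycle, metabolism, the clock and reference genes.

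The genes named in the text follow a rule fixed before the data were examined. It takes the 8 genes with the largest rise and the 8 with the largest fall among those called whose groups did not overlap and that carry a gene symbol and not a clone name. It adds the members with the smallest p of each list, up to 4 where the list was called or had at least 3 called members and otherwise 2, and 18 genes of ferroptosis, oxidant defence and vessels named in advance. Where 5 or fewer members of a list were called, or where most called members of a list are spelled out, members outside this rule are also named, and these were chosen after their values were seen.

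The procedure was tested on simulated data with the real genes (15202 genes run). Noise was drawn from limma's moderated variance of each gene, equal in both groups, with counting noise at the depth that is not established. The procedure called 79.2% of 96 genes changed 2-fold and 28.3% of 99 genes changed 1.41-fold, and 5 of 109 calls were false. These rates hold for that noise and may differ in the real libraries. With no change simulated, 0 genes were called. A list shifted as a whole was called and 0 of 38 other lists were. The simulated genes varied independently of each other and the lists were random. List calls were therefore not tested for members that vary together, as in the cell cycle list (estimated correlation 0.44).

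Alternatives fixed before the data were examined were the pseudocount (0.1 and 0.5), no filter or a mean of at least 5 FPKM, rescaling to TPM, median-ratio scaling, quantile normalization, limma without the trend or with robust moderation, the replicate number as a block, the other list tests, and leaving out each library in turn. Removal of a gene length trend (loess, span 0.3) and cyclic loess normalization were added after seeing the data. Further lists made once the data had been examined serve only the hypotheses at the end, and 1 member (mt2) was removed from the glucocorticoid list of these after its result was known. Reference sequence was not used here, so GC content was not examined. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 read the table and drew the plots. No batch, date or lane is given in the labels, so no batch could be modelled.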

Results

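Gene expression was measured by poly(A) RNA sequencing in the heads of zebrafish embryos at 2 days post-fertilization (dpf). One group had been kept in 500 µg/L 6PPD, an antioxidant added to tire rubber, from 10 hours post-fertilization (hpf), and the other group in the solvent DMSO. Each group held 3 biological replicates, and each replicate pooled 150 dissected heads, so the libraries carry RNA of brain, eye, skin, vessels and cranial muscle although the labels name the tissue as brain. All embryos received the pigment inhibitor PTU (0.003% from 24 hpf). The design implies a single comparison, 6PPD against DMSO. The title of the series names cerebrovascular development, oxidative stress and ferroptosis (iron-dependent cell death by lipid peroxidation) as its subject. Each library is given as one FPKM value (fragments scaled by gene length and library size) for each of 32057 genes, and read totals are not part of the table. The commonest low value of FPKM times length in a preset window would give 14.3 to 16.5×10⁶ units per library, if it is 1 fragment. Low values were whole multiples of it in 23.3% to 25.7% of cases, where an arbitrary step gives 20%. This depth is therefore not established. If it held, a 2 kb gene at 1 FPKM would rest on about 28.6 to 33 fragments. That would be a counting error of 17.4% to 18.7%, which covers counting alone.

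In 6PPD heads the mitotic kinase gene cdk1, the chaperone genes serpinh1b and hsp90aa1.2 and the ferritin-like gene fthl31 rose, and the transcription factor genes cebpb, cebpd and fosl1a, the prostaglandin synthase gene ptgs2a, the rod opsin gene rho and the clock gene per1b fell. Of 15320 genes tested (mean of at least 1 FPKM), 522 differed in limma at an adjusted p under 0.05, 346 of them higher and 176 lower in 6PPD. The change reached a doubling in 29 and a halving in 51. In 4023 genes (26.3%) the 3 libraries of one group did not overlap the 3 of the other, where chance gives 10%. The share of higher genes among the calls, 66.3%, was 75.1% after rescaling to TPM, 50.5% after median-ratio scaling, 52.9% after quantile normalization, 50.6% after removal of a gene length trend and 51.5% after cyclic loess. With no filter on low values, 13 genes were called higher and 13 lower.

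**Figure D1:**
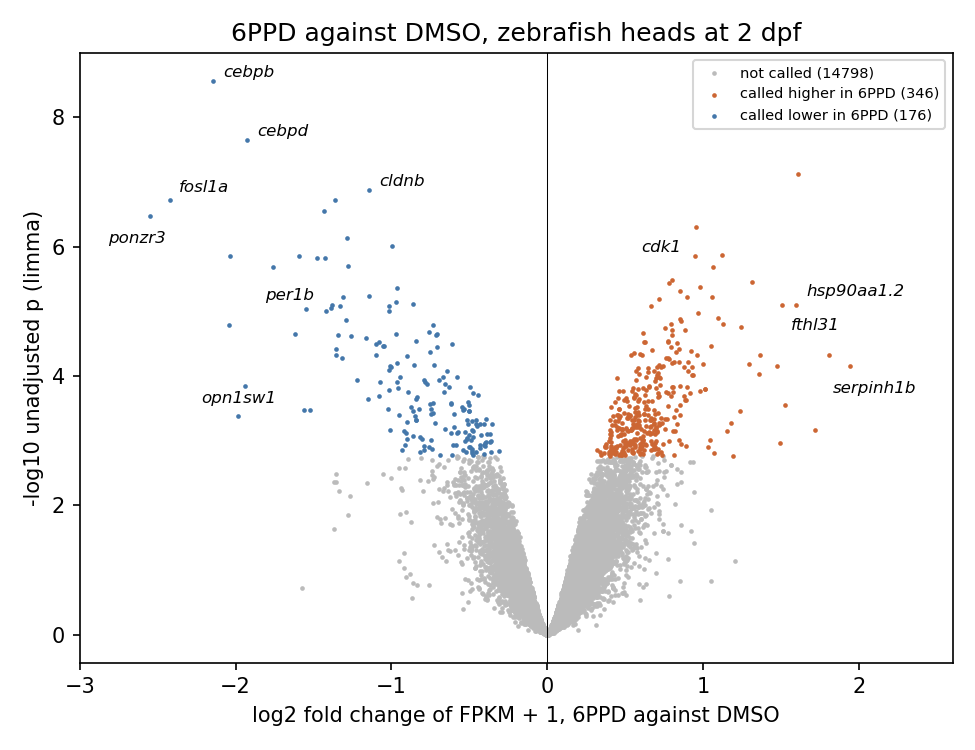
Log2 fold change of FPKM + 1 in 6PPD against DMSO (3 libraries each) and −log10 of limma's unadjusted p for 15320 genes, with the 346 called higher in orange and the 176 called lower in blue. The points at the far left include ponzr3, fosl1a, cebpb and cebpd, and the point at the far right is serpinh1b.

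The third DMSO library lay between the other controls and the 6PPD libraries on the first principal component. That component (43.5% of the variance) placed the 6PPD libraries at 15.3 to 16.9, DMSO replicates 1 and 2 at -20.6 and -22.8, and DMSO replicate 3 at -4.7. The median absolute log2 difference from DMSO replicate 3 was 0.157 to 0.171 for the 6PPD libraries, against 0.197 and 0.184 for DMSO replicates 1 and 2. Its Pearson correlation was higher with DMSO replicates 1 and 2 (0.982 and 0.985) than with the 6PPD libraries (0.981 each). Without DMSO replicate 3, 805 genes were called higher and 325 lower. The counts were 88 and 80 without DMSO replicate 2, 85 and 99 without 6PPD replicate 1, 130 and 80 without 6PPD replicate 2, and 97 and 72 without 6PPD replicate 3. Genes with at least a doubling numbered 18 without 6PPD replicate 1. Of 83 called genes picked by the rule for naming genes, 37 were called in all 6 of these fits with 1 library left out, and 46 lost the call in at least 1. The 37 are cebpb, cebpd, fosl1a, ponzr3, ponzr4, dhrs13a.2, ptgs2a, ptgs2b, atf3, foxq1a, chac1, slc3a2b, acsl4a, abca1a, igfbp1a, cldnb, rho, per1b, nr1d2b, ciarta, cry-dash, cdk1, tk1, ccne2, cdc25b, serpinh1b, hsp90aa1.2, dnaja1, fthl31, cox4i1l, rsrp1, gstp1, eno1a, ldha, p4ha1b, p4ha2 and stmn1a.

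The genes with the largest falls were ponzr3, a plac8 onzin-related gene (log2 fold change -2.55 ± 0.21, SE), and fosl1a, which encodes the AP-1 subunit Fra-1. The level of fosl1a (ENSDARG00000015355, chromosome 14, 30739476 to 30747686) fell from 8.33 ± 2.33 to 0.711 ± 0.121 FPKM (SD, n = 3 per group). The C/EBP transcription factor genes cebpb (ENSDARG00000042725, chromosome 8, 28448267 to 28449782) and cebpd (ENSDARG00000087303, chromosome 24, 35564668 to 35565927), regulators of acute-phase and inflammatory genes, fell from 53 ± 6.89 to 11.2 ± 0.353 FPKM and from 49.7 ± 8.22 to 12.3 ± 0.766 FPKM, with limma adjusted p = 4.19e-05 and 0.000175. The other large falls were in ponzr4 (-2.04), the dehydrogenase gene dhrs13a.2 (-2.04), the ultraviolet cone opsin opn1sw1 (-1.98), and fkbp5 (-1.94), a co-chaperone of the glucocorticoid receptor. The largest rise was in serpinh1b (ENSDARG00000019949, chromosome 15, 29382454 to 29388012), the collagen chaperone Hsp47, from 34.5 ± 14.8 to 126 ± 20.2 FPKM (log2 fold change 1.94 ± 0.29, limma adjusted p = 0.00947). It was followed by hsp90aa1.2 (1.6), hsp70.3 (1.52), the ferritin heavy chain-like gene fthl31 (1.51), ggact.3 (1.49), rsrp1 (1.47), the cytochrome c oxidase subunit gene cox4i1l (1.37) and fthl28 (1.36). Values of the ponzr, hsp70, hsp90 and fthl genes are uncertain, because fragments may be divided between similar copies. The similarity of the copies was not examined. The level of ggact.3 in DMSO was 0.557 ± 0.905 FPKM, below the filter value.

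Of 63 cell cycle genes tested, 32 rose (48 higher and 1 lower when adjusted over the list alone), and 62 had a positive log2 fold change. The mitotic kinase gene cdk1 (ENSDARG00000087554, chromosome 17, 20923691 to 20929461) rose from 61.3 ± 5.85 to 119 ± 7.11 FPKM (log2 fold change 0.95 ± 0.09, limma adjusted p = 0.00138). Thymidine kinase tk1 rose from 5.71 ± 0.573 to 13 ± 0.882 FPKM, cyclin E2 (ccne2) from 14.6 ± 0.807 to 25.8 ± 1.07 FPKM, and the CDK-activating phosphatase cdc25b from 11.5 ± 1.08 to 21.4 ± 0.897 FPKM. The list had mean log2 fold change 0.48 ± 0.25 (SD over members), camera adjusted p = 3.79e-21, and adjusted p = 0.376 with an estimated correlation. Of 43 neural progenitor markers, which had a median log2 fold change of 0.07, 1 rose, the Hairy/E(spl) gene hes2.2 (0.40; adjusted over the list alone, 4 higher and 2 lower; camera adjusted p = 0.933).

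A part of the inflammation genes fell. Of 36 inflammation and interferon genes, 11 fell (12 adjusted over the list alone). These were fosl1a, cebpd, fosab, junba, junbb, nfkbiaa, socs3a, socs3b, mmp9 and the prostaglandin synthase genes ptgs2a and ptgs2b. The gene ptgs2b fell from 7.64 ± 0.171 to 2.21 ± 0.256 FPKM and ptgs2a from 17.8 ± 2.2 to 8.57 ± 0.0686 FPKM (limma adjusted p = 0.000623 and 0.00268). The list had mean log2 fold change -0.42 ± 0.68 (SD over members), camera adjusted p = 4.73e-08, and adjusted p = 0.376 with an estimated correlation, and its median was -0.13 (all tested genes 0.06). Its mean was -0.26 with no filter on low values. It was the one list that fry called (adjusted p = 0.043). Among 25 microglia, macrophage and neutrophil markers 4 fell (adjusted over the list alone, 0 higher and 4 lower), namely cebpb, mmp9 (-1.07), apoeb (-0.40) and lysozyme (lyz, -0.82). Of these cebpb and mmp9 are not restricted to these cells. The marker list had mean log2 fold change -0.19 ± 0.53 (SD over members), camera adjusted p = 0.00219, and adjusted p = 0.376 with an estimated correlation, with a mean of -0.09 with no filter on low values and -0.48 at a mean of at least 5 FPKM. Of 58 genes of the unfolded protein and integrated stress response, 4 fell (adjusted over the list alone, 2 higher and 7 lower), namely cebpb, chac1, atf3 (-1.32) and sesn2 (-0.79). That list had mean log2 fold change -0.08 ± 0.41 (SD over members), camera adjusted p = 0.0147, and adjusted p = 0.464 with an estimated correlation, and adjusted p = 0.156 without DMSO replicate 1, 0.146 after quantile normalization and 0.118 after cyclic loess. Epidermis and periderm markers were lower in 6PPD too (mean log2 fold change -0.32, and -0.19 without DMSO replicate 1). Among the controls they did not follow the inflammation list. In DMSO replicates 1 to 3 the epidermal list had mean log2 levels of 5.24, 4.89 and 4.80, and the inflammation list 2.66, 2.78 and 2.79.

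**Figure D2:**
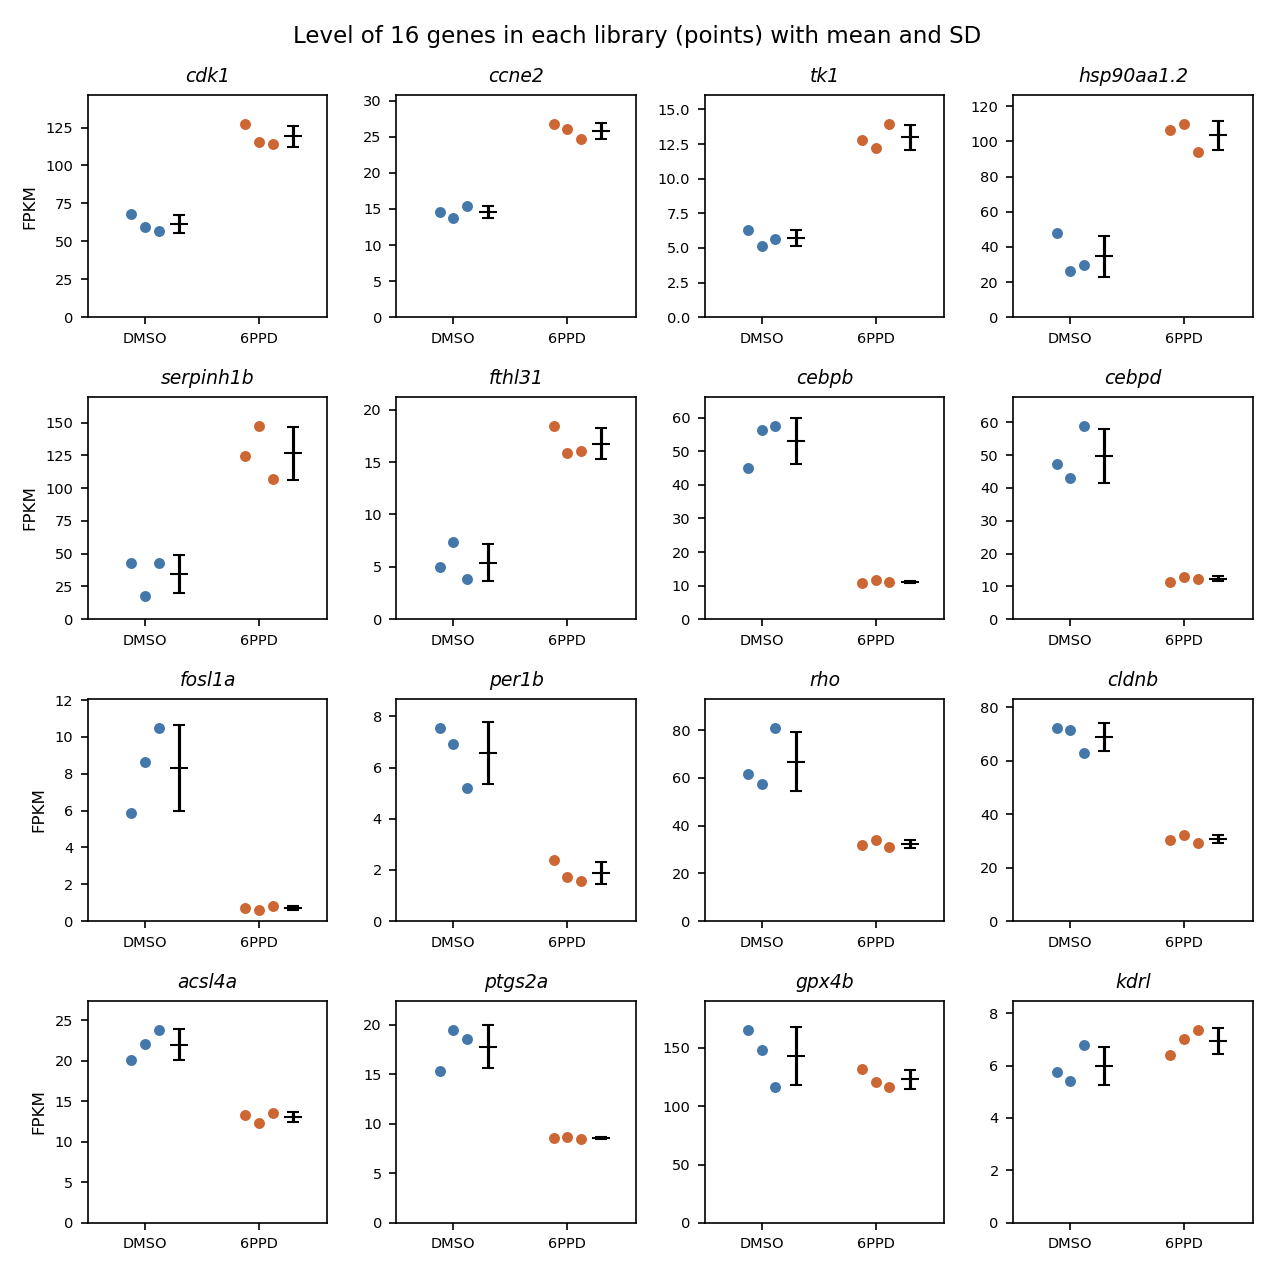
FPKM of 16 genes in each library (points, 3 per group; DMSO blue, 6PPD orange), with the mean and SD of each group in black, on linear axes from 0. The groups are separate for the first 14 genes, for example 45.1 to 57.6 FPKM against 10.9 to 11.6 FPKM for cebpb, and they overlap for kdrl and gpx4b.

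Genes tied to ferroptosis changed in both directions, and most members were not called. Of 27 ferroptosis-promoting genes and markers, 4 fell and 2 rose (5 and 3 adjusted over the list alone). Of all tested genes, 3.41% were called. The acyl-CoA synthetase gene acsl4a (ENSDARG00000004078, chromosome 14, 28438947 to 28459446), whose product couples arachidonic acid to coenzyme A, fell from 22 ± 1.91 to 13.1 ± 0.662 FPKM (log2 fold change -0.71 ± 0.09, limma adjusted p = 0.00563). The marker genes ptgs2a (ENSDARG00000004539, chromosome 2, 20916497 to 20923864) and ptgs2b, and the glutathione-degrading enzyme gene chac1 (-0.76), fell as well, while the spermidine acetyltransferase gene sat1b (0.71) was among those that rose. Fry's mixed test gave adjusted p = 2.27e-05 for the promoting list, and also a low value for other lists, such as neural progenitor markers (0.000175). The promoting list had mean log2 fold change -0.10 ± 0.46 (SD over members), camera adjusted p = 0.0259, and adjusted p = 0.376 with an estimated correlation. Its camera adjusted p was 0.064 without DMSO replicate 1, 0.0574 without DMSO replicate 2, 0.141 at a mean of at least 5 FPKM, 0.0959 after quantile normalization and 0.097 after cyclic loess. Of 32 ferroptosis-suppressing genes, 2 fell (adjusted over the list alone, 1 higher and 3 lower), slc3a2b, the heavy chain of the cystine transporter and of other amino acid transporters (-0.73), and the transsulfuration enzyme gene cbsb (-0.66), with camera adjusted p = 0.0722, and 0.0357 without DMSO replicate 3. The lipid peroxide reductase genes did not pass the threshold: gpx4a measured 6.69 ± 1.36 FPKM in DMSO and 7.1 ± 0.522 FPKM in 6PPD, and gpx4b 143 ± 25 FPKM in DMSO and 123 ± 8.15 FPKM in 6PPD (limma adjusted p = 0.743 and 0.388). The cystine transporter gene slc7a11 lay below the filter, at 0.725 ± 0.299 FPKM in DMSO and 0.774 ± 0.103 FPKM in 6PPD.

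A few iron handling and antioxidant genes rose. Of 22 iron handling genes, 3 rose (5 adjusted over the list alone), namely fthl31, fthl28 and biliverdin reductase blvrb (0.62), and the iron exporter gene slc40a1 had a log2 fold change of 0.38 (limma adjusted p = 0.0722, and 0.0301 without DMSO replicate 3). The list had mean log2 fold change 0.29 ± 0.42 (SD over members), camera adjusted p = 0.0259, and adjusted p = 0.376 with an estimated correlation, and adjusted p = 0.189 without DMSO replicate 3. The main ferritin gene fth1a (0.09), the transferrin receptor gene tfr1b (0.22) and the heme oxygenase gene hmox1a (-0.01) were not called, with limma adjusted p = 0.716, 0.292 and 0.977. Of 31 Nrf2 targets, 4 rose (adjusted over the list alone, 5 higher and 3 lower), gstp1 from 394 ± 39.9 to 679 ± 68.5 FPKM, peroxiredoxin prdx1 (0.80), thioredoxin txn (0.67) and blvrb (camera adjusted p = 0.564). Of 33 oxidant-detoxifying enzymes, 4 rose (adjusted over the list alone, 4 higher and 0 lower), with selenop (0.58) and glrx (0.52) beside prdx1 and txn (camera adjusted p = 0.927). The NAD(P)H quinone reductase gene nqo1 (-0.22), superoxide dismutase sod1 (-0.13) and catalase cat (-0.00) were not called (limma adjusted p = 0.384, 0.459 and 0.986). Of 30 glutathione transferases and conjugating enzymes, gstp1 and ugt1a1 (0.77) rose (camera adjusted p = 0.854; adjusted over the list alone, 3 higher and 2 lower). Of 15 aryl hydrocarbon receptor targets, gstp1 rose and foxq1a (-1.48) fell (camera adjusted p = 0.798; adjusted over the list alone, 1 higher and 1 lower), and cyp1a measured 258 ± 18 FPKM in DMSO and 228 ± 2.61 FPKM in 6PPD (limma adjusted p = 0.267). Among 17 other cytochrome P450 genes, cyp2aa1 (0.68) rose and the vitamin D hydroxylase gene cyp24a1 (-0.72) fell (camera adjusted p = 0.695; adjusted over the list alone, 3 higher and 3 lower).

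Few vessel genes were called. Of 42 endothelial markers, plvapb, which encodes a protein of vessel wall diaphragms, fell from 14.5 ± 1.14 to 10.7 ± 0.491 FPKM (limma adjusted p = 0.0489). The receptor gene kdrl measured 5.98 ± 0.709 FPKM in DMSO and 6.92 ± 0.491 FPKM in 6PPD, and the log2 fold changes of cdh5 (0.08 ± 0.14, SE) and pecam1 (0.18 ± 0.12) were within the spread between libraries, with limma adjusted p = 0.39, 0.763 and 0.429. Adjusted over the list alone, 0 endothelial markers were higher and 0 lower. The list averaged 0.14 ± 0.18 (SD over members), and 34 members had a positive log2 fold change. The median log2 fold change of all tested genes was 0.06. Over the other settings the endothelial mean ranged from 0.05 to 0.21. The mean of each 6PPD library lay above that of each DMSO library, and 16 of the 39 lists separated in this way, in either direction. The camera adjusted p of the endothelial list was 0.0927, and 0.0171 toward higher with no filter on low values. The phosphatase gene ptprb (0.54, limma adjusted p = 0.0683) was called higher without DMSO replicate 3 (0.66, adjusted p = 0.0219). No member of 50 angiogenic signalling genes was called by limma, and 8 were higher at an unadjusted p under 0.05. Of these notch1a (0.27) and pdgfba (0.60) had the smallest p. Among all 15320 genes tested, 3113 had an unadjusted p under 0.05 in either direction. The growth factor gene vegfaa was at -0.05 (list camera adjusted p = 0.118, fry adjusted p = 0.284). Of 39 brain vessel barrier and transport genes, the Wnt co-receptor gene lrp6 rose (0.34), and the claudin gene cldn5a (0.50 ± 0.21) and the lipid transporter gene mfsd2aa (-0.14 ± 0.13) were not called (limma adjusted p = 0.217 and 0.567). Without DMSO replicate 3, cldn5a was called higher (0.74, adjusted p = 0.0334). The barrier list had camera adjusted p = 0.829 (adjusted over the list alone, 0 higher and 0 lower). Of 17 mural cell markers none was called by limma and 1 was higher at an unadjusted p under 0.05 (camera adjusted p = 0.927, fry adjusted p = 0.636), with pdgfrb at 0.43. Vessel transcripts were measured together with those of all other head tissues.

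Part of the heat shock and of the hypoxia-responsive genes rose. Of 38 heat shock and protein folding genes, 10 rose and 2 fell (15 and 2 adjusted over the list alone). The gene hsp90aa1.2 (ENSDARG00000024746, chromosome 20, 53967350 to 53981626) rose from 34.6 ± 11.6 to 103 ± 8.4 FPKM, and the Hsp40 genes dnaja1 and dnajb1b rose by 0.96 and 0.93 on the log2 scale, while fkbp5 and hsf2 fell. The list had mean log2 fold change 0.33 ± 0.66 (SD over members), camera adjusted p = 0.00219, and adjusted p = 0.435 with an estimated correlation, and adjusted p = 0.093 without DMSO replicate 3. Of 54 hypoxia-responsive genes, 5 rose, the glycolytic genes eno1a (0.61) and ldha (0.54), the collagen prolyl hydroxylase genes p4ha2 (0.81) and p4ha1b (0.93), and egln3, and 2 fell, igfbp1a (-1.05) and pfkfb4b (adjusted over the list alone, 13 higher and 3 lower). That list had mean log2 fold change 0.17 ± 0.35 (SD over members), camera adjusted p = 0.0291, and adjusted p = 0.669 with an estimated correlation, and adjusted p = 0.0973 without DMSO replicate 1 and 0.076 without 6PPD replicate 2. The same 2 hydroxylase genes were the called members among 67 extracellular matrix genes (adjusted over the list alone, 2 higher and 0 lower; camera adjusted p = 0.63, mean log2 fold change 0.05, and -0.04 with adjusted p = 0.0355 toward lower without DMSO replicate 2).

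Some light-sensing, pigment and clock genes fell. Of 43 photoreceptor and retina genes, 5 fell (13 lower and 4 higher adjusted over the list alone): the rod opsin gene rho fell from 66.8 ± 12.5 to 32.2 ± 1.53 FPKM (limma adjusted p = 0.00354), joined by cone arrestin arr3a (-1.02), recoverin rcvrn3 (-0.89), opn1sw1 and rod transducin gnat1. The retinal list had mean log2 fold change -0.34 ± 0.47 (SD over members), camera adjusted p = 5.74e-09, and adjusted p = 0.488 with an estimated correlation, and its mean was -0.20 without DMSO replicate 3 and -0.23 at a mean of at least 5 FPKM. Of 28 pigment cell genes, 5 fell (9 adjusted over the list alone), among them the retinoid isomerase gene rpe65a (-0.79), the melanosome genes slc45a2 (-0.48) and gpr143 (-0.61), and pnp4a (-0.45) of iridophores. The pigment list had mean log2 fold change -0.26 ± 0.28 (SD over members), camera adjusted p = 4.73e-08, and adjusted p = 0.376 with an estimated correlation. Pigment formation was inhibited in both groups by PTU. Of 40 circadian clock genes, 7 fell (12 adjusted over the list alone). The nuclear receptor gene nr1d2b fell from 19 ± 1.13 to 9.03 ± 0.533 FPKM and the period gene per1b from 6.56 ± 1.21 to 1.89 ± 0.425 FPKM, and ciarta (-0.72) and cry-dash (-0.85) fell too. The clock list had mean log2 fold change -0.21 ± 0.42 (SD over members), camera adjusted p = 7.92e-07, and adjusted p = 0.376 with an estimated correlation.

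Camera called the epidermis, liver and yolk, and skeletal muscle lists lower with the preset correlation, and few of their members fell. Of 48 epidermis and periderm genes, 3 fell (11 adjusted over the list alone), the claudins cldnb, from 68.9 ± 5.15 to 30.6 ± 1.51 FPKM, and cldne (-0.46), and agr1 (-0.93), and 43 members had a negative log2 fold change. The epidermal list had mean log2 fold change -0.32 ± 0.29 (SD over members), camera adjusted p = 1.38e-11, and adjusted p = 0.464 with an estimated correlation. The epidermal mean was -0.19 without DMSO replicate 1. All 10 genes tested of the liver and yolk syncytial layer list had a negative log2 fold change, and the retinol carrier gene rbp4 fell (-0.76; adjusted over the list alone, 0 higher and 1 lower). Of the 10, 4 were copies of ctslb, which is not specific to these tissues, and the copies cannot be told apart with certainty. The fall of this list is therefore not a measure of liver or yolk alone. The liver and yolk list had mean log2 fold change -0.66 ± 0.30 (SD over members), camera adjusted p = 0.000486, and adjusted p = 0.376 with an estimated correlation, with a mean of -0.19 with no filter on low values and -1.01 with a pseudocount of 0.1. Of 50 skeletal muscle genes, myl13 (-0.36) and gapdh (-0.48) fell (adjusted over the list alone, 0 higher and 3 lower). The muscle list had mean log2 fold change -0.12 ± 0.22 (SD over members), camera adjusted p = 0.000112, and adjusted p = 0.524 with an estimated correlation. The muscle mean was -0.08 without DMSO replicate 3, -0.23 without 6PPD replicate 1 and -0.04 without 6PPD replicate 3, and the 6PPD and DMSO library means overlapped. The reference genes in common use were slightly lower, with gapdh called and actb1 (-0.32) and rpl13a (-0.22) not (adjusted over the list alone, 0 higher and 1 lower; mean log2 fold change -0.10 ± 0.16 (SD over members), camera adjusted p = 0.0107, and adjusted p = 0.396 with an estimated correlation), and adjusted p = 0.0698 without DMSO replicate 2, 0.501 after quantile normalization and 0.457 after cyclic loess. Without DMSO replicate 3, actb1 and rpl13a were called lower (adjusted p = 0.0483 and 0.0494).

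Few energy and sterol genes were called. Of 77 nuclear oxidative phosphorylation genes, the 2 called, the cytochrome c oxidase genes cox6b1 (0.59) and cox4i2 (0.58), rose, although the list lay lower (adjusted over the list alone, 2 higher and 0 lower; mean log2 fold change -0.12 ± 0.17 (SD over members), camera adjusted p = 1.16e-08, and adjusted p = 0.605 with an estimated correlation). That mean was -0.06 without DMSO replicate 2, -0.21 without DMSO replicate 3 and -0.08 without 6PPD replicate 3, and the library means of the groups overlapped. None of 13 mitochondrially encoded genes was called by limma, with 1 lower at an unadjusted p under 0.05, and the list lay lower (adjusted over the list alone, 0 higher and 0 lower; mean log2 fold change -0.12 ± 0.10 (SD over members), camera adjusted p = 0.00657, and adjusted p = 0.509 with an estimated correlation, and fry adjusted p = 0.265). Its camera adjusted p was 0.0731 without 6PPD replicate 1. Its mean was 0.01 after quantile normalization and after cyclic loess (camera adjusted p = 0.916 and 0.849). Without DMSO replicate 3, mt-nd3 was called lower (-0.47, limma adjusted p = 0.0164). Among 30 cholesterol genes, the efflux transporter gene abca1a (-0.71) and the receptor gene ldlrb (-0.58) fell (adjusted over the list alone, 0 higher and 2 lower; mean log2 fold change -0.11 ± 0.29 (SD over members), camera adjusted p = 0.00248, and adjusted p = 0.464 with an estimated correlation). That mean was -0.05 without DMSO replicate 3, and the adjusted p was 0.0991 at a mean of at least 5 FPKM.

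Single neuronal genes rose, and the neuronal list did not pass the threshold. Of 64 neuron and synapse genes, 4 rose (7 adjusted over the list alone), stmn1a from 77.8 ± 3.1 to 118 ± 9.85 FPKM, the pan-neuronal RNA-binding gene elavl3 (0.64), snap25a (0.40) and neflb (0.48), with camera adjusted p = 0.0548. That value was 0.0383, 0.0189, 0.026 and 0.00266 without 6PPD replicates 1 and 3 and DMSO replicates 2 and 3. The mean log2 fold change was 0.14, and 0.23 without DMSO replicate 3. It was 0.08 after median-ratio scaling, and 0.06 in the setting that gave the lowest mean. The adjusted p was 0.0153 with no filter on low values, 0.0428 after median-ratio scaling, 0.0141 after quantile normalization and 0.0121 after cyclic loess, all toward higher. Among 42 fatty acid and lipid genes, lpl (0.40), its second listed copy LPL (0.71) and pdk4 (0.70) rose and acsl4a fell (camera adjusted p = 0.561; adjusted over the list alone, 4 higher and 1 lower). In the erythroid list (26 genes) blvrb rose (adjusted over the list alone, 1 higher and 0 lower; camera adjusted p = 0.213, and 0.0122 toward lower without DMSO replicate 3), and in the thyroid hormone list (11 genes) klf9 fell (-0.85; adjusted over the list alone, 0 higher and 1 lower; camera adjusted p = 0.958). No gene was called by limma among 39 lens, 40 cartilage, 15 oligodendrocyte and 11 cardiac muscle genes. Of these 2, 4, 1 and 2 had an unadjusted p under 0.05, as did 3113 of all 15320 genes. The lists had camera adjusted p of 0.888, 0.26, 0.542 and 0.577, and fry called none. Without DMSO replicate 3, the lens genes cryaa (0.74) and crybgx (0.82) were called higher (limma adjusted p = 0.0416 and 0.0428). The lens list was called in opposite directions without 6PPD replicate 2 (mean log2 fold change -0.11, adjusted p = 0.000318) and without 6PPD replicate 3 (0.19, adjusted p = 0.0307).

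**Figure D3:**
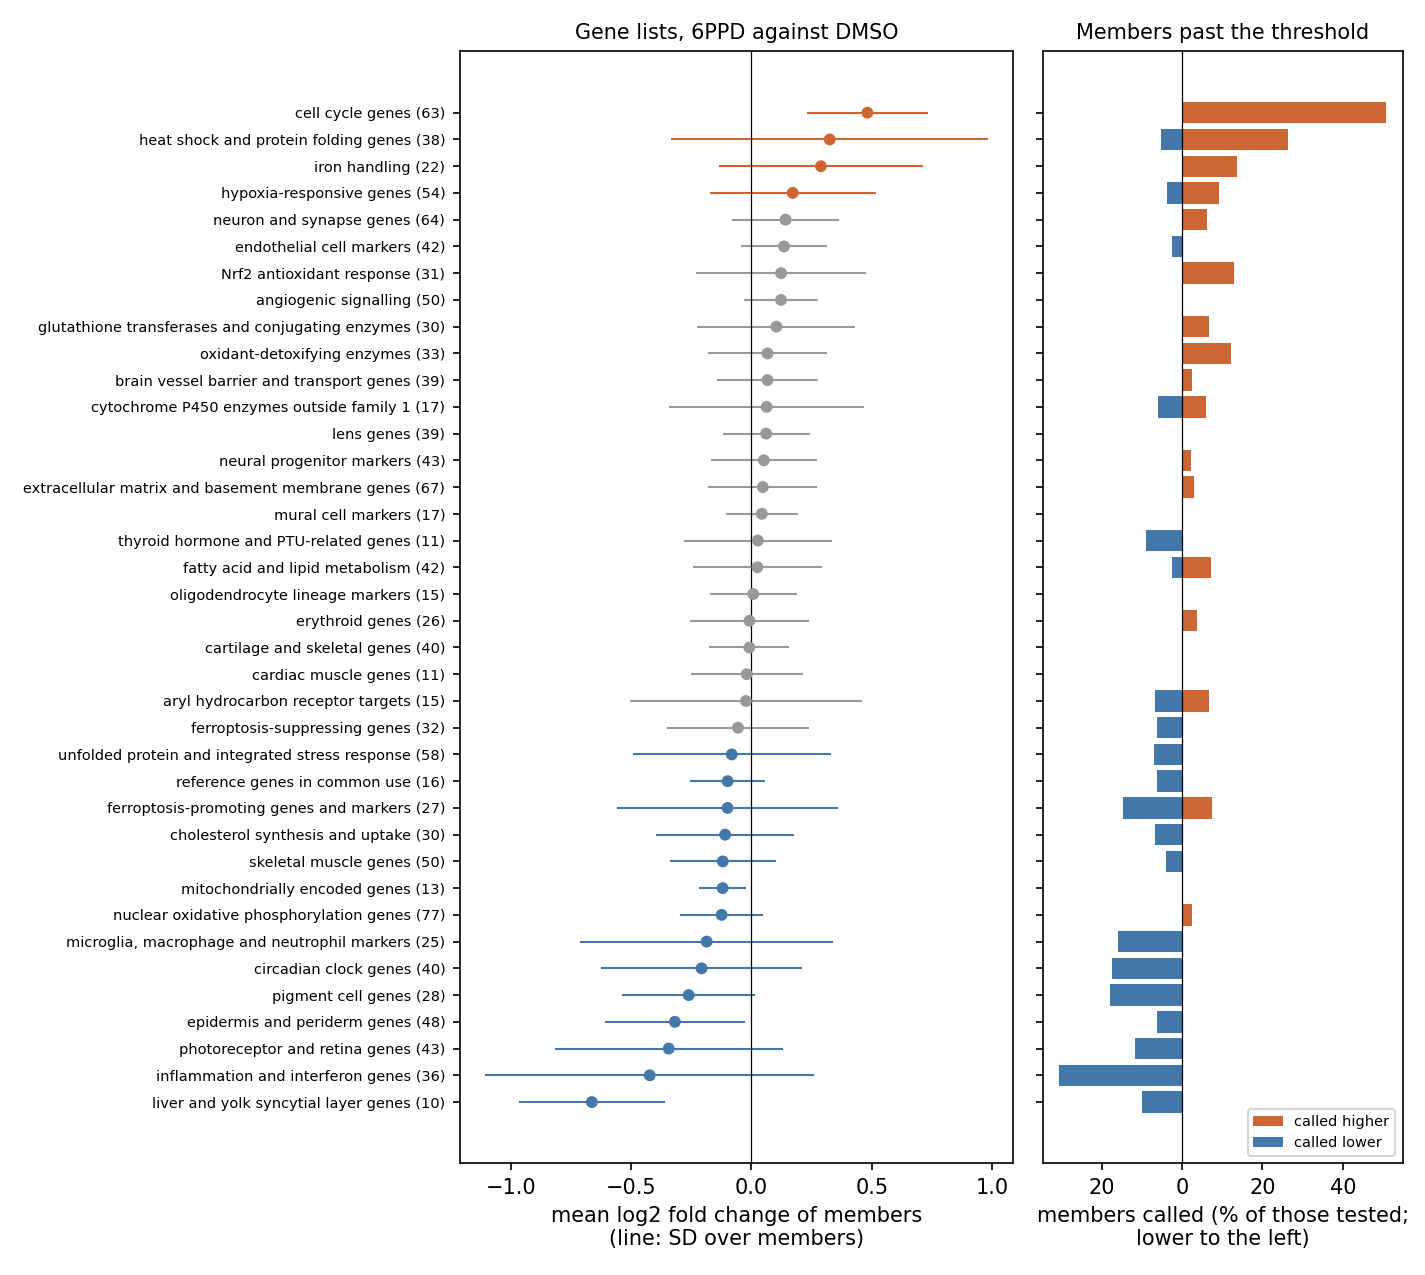
For 38 of the gene lists (members tested in parentheses), left, the mean log2 fold change of FPKM + 1 in 6PPD against DMSO (point) and its SD over members (line), orange or blue where camera called the list higher or lower, and right, the percent of members called by limma. The cell cycle list stands at the top with a mean of 0.48, and the liver and yolk syncytial layer list at the bottom with -0.66.

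Of the 39 lists, camera with a preset correlation called 4 higher and 14 lower, and 10 lower after quantile normalization and after cyclic loess. With an estimated correlation 0 were called (lowest adjusted p = 0.376, 3 lists at an unadjusted p under 0.05), and fry called 1. Rescaling to TPM and median-ratio scaling moved small list means in opposite directions, to -0.07 and -0.19 for the nuclear oxidative phosphorylation list, -0.07 and -0.19 for the mitochondrially encoded list, -0.05 and -0.16 for the reference list, -0.03 and -0.14 for the unfolded protein list and -0.06 and -0.16 for the ferroptosis-promoting list. The skeletal muscle mean was -0.08 after rescaling to TPM and -0.08 with no filter, and the cholesterol mean -0.18 after quantile normalization, -0.17 after removal of the length trend and -0.19 after cyclic loess. Removal of the length trend gave -0.15, -0.14 and -0.16 for the reference, unfolded protein and ferroptosis-promoting lists. Camera with the preset correlation also called 8 to 17 lists when the 6 libraries were divided 3 and 3 in the other 9 ways, in which limma called 0 genes (163 to 1273 at an unadjusted p under 0.05).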

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

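Among the settings, removal of the gene length trend and cyclic loess were chosen after seeing the data. The 522 genes called kept the sign of their change under every setting in which they were tested. For the fits with 1 library left out this was fixed in advance, because the groups of all 522 did not overlap. The filter, trend, moderation and block settings do not alter the fold change. With 1 library left out, 160 to 477 of the 522 were still called. With no filter on low values, 13 genes were called higher, 13 lower, 3 with a doubling and 10 with a halving, with 26983 genes tested and prior degrees of freedom 2.21 against 5.56. Limma without the trend called 214 higher. Genes called higher with at least a doubling numbered 60 with a pseudocount of 0.1 and 55 after rescaling to TPM and 17 at a mean of at least 5 FPKM. Gene lists called were 0 higher and 0 lower with an estimated correlation, and 0 higher and 1 lower with fry. With 1 library left out, genes called ranged from 85 to 805 higher and from 72 to 325 lower, 18 to 39 with a doubling and 39 to 61 with a halving, and lists from 3 to 6 higher and 12 to 16 lower. Camera's direction differed from the reported one, with a call in at least 1 of the fits compared, in 2 lists. The mitochondrially encoded list had a mean of 0.00768 after quantile normalization and 0.0098 after cyclic loess, and the lens list a mean of 0.186 without 6PPD replicate 3 and -0.109 without 6PPD replicate 2, and the cause was not tested. Over all settings, the 132 named genes tested gave 1992 values on the same side of the threshold as reported, 318 that lost and 27 that gained a call, and 0 that changed direction with a call. With the replicate number as a block, 281 genes were called higher and 174 lower, with 4 lists higher and 14 lower. Samples with the same number did not deviate together (correlations 0.0301, 0.181 and -0.0257), so the numbers are not taken as pairs.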

Other observations

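Chosen only after the results were seen were the genes named in this paragraph and the next and the tests on neural progenitors, developmental progress, epidermal share, handling and other splits of the libraries, and the glucocorticoid list in the form reported. The linker histone gene histh1l fell from 1442 ± 264 to 475 ± 60.2 FPKM and h1-10 from 109 ± 19.5 to 44.2 ± 4.12 FPKM (limma adjusted p = 0.00138 and 0.00158), and the core histone variant gene h2ax fell by 0.69 on the log2 scale. The replacement histone genes h3f3c (0.08) and h2az2a (-0.03) were not called. Of genes linked to amino acid supply, not tested as a group, the transporter genes slc7a3a (-0.63) and slc1a4 (-0.51) and the isoleucyl-tRNA synthetase gene iars1 (-0.48) fell, and asns (0.09), psat1 (-0.01) and ddit3 (0.36), were not called.

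Nucleolar genes were among those called lower, including gar1 (-0.43), rrp1 (-0.59), rrp12 (-0.48), krr1 (-0.50), sdad1 (-0.46) and pwp1 (-0.50). The hypothesis that ribosome biogenesis genes are lower as a class was tested on a separate list that left these out, written before its values were seen. Of 67 members, 57 had a negative log2 fold change, with a mean of -0.155 ± 0.0255 (SE over members) and an unadjusted camera p = 4.83e-13, 0.0425 with an estimated correlation. The real division of the libraries gave a larger distance of this list from all genes (-0.212) than the other 9 divisions (at most 0.119). The same held for lists with small changes, such as reference genes and aryl hydrocarbon receptor targets, so it does not set the ribosome biogenesis list apart. A small shared decrease of this class in 6PPD may account for the pattern, and the SE treats members as independent, which they are not.

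The higher cell cycle genes (mean log2 fold change 0.48) had 3 explanations weighed. A gene length trend between libraries is argued against, since the mean stayed at 0.422 once each library's length trend was removed. A larger share of neural progenitor cells is argued against, since the median of progenitor markers was 0.0669 (SD over members 0.22) against 0.49 for the cell cycle list. Slower developmental progress of the 6PPD heads may contribute and stays open: phototransduction genes averaged -0.58 ± 0.11 (SE) and early retinal genes 0.02 ± 0.07, a difference of 0.601, but early genes were not higher as a delay would need. A direct effect of 6PPD on cell division was not tested.

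A set of immediate-early and C/EBP genes, put together mainly from genes already seen lower, had a median log2 fold change of -1.32 over 13 genes (11 called lower; egr1 at -0.43 and jun at 0.12 were not called). A smaller share of all epidermal cells alike is argued against as the whole cause. It needs the epidermis and periderm markers, a list fixed in advance, to fall about as far, and their median was -0.31 (SD 0.29). The gap between these medians is widened by selection, because the pattern's set was picked for its falls. In the epidermal list cldnb was at -1.14, and 5 of 48 members were above 0. A smaller share of only some epidermal cells was not tested. More handling stress in the DMSO heads before freezing may account for the pattern and cannot be told apart from an effect of 6PPD, because heat shock genes were higher in 6PPD (mean 0.325) and so do not report on handling in DMSO. Lower glucocorticoid receptor activity may contribute, since fkbp5, klf9 and per1b were lower. The other 12 glucocorticoid-responsive genes averaged -0.114 ± 0.0643 (SE), which is within 2 SE of 0 and leaves the question open. Their unadjusted camera p was 0.0158, and 0.0812 with an estimated correlation, and their unadjusted fry p was 0.0366. The distance of this list from all genes (-0.171) was larger than in the other 9 divisions of the libraries (at most 0.114). As this also held for lists with small changes, such as reference genes, it does not set the glucocorticoid list apart. That list was changed after its result was known: as first run it held mt2 too (13 genes, mean -0.137 ± 0.0636) and met the bound for this explanation, more than 2 SE below 0, and mt2 was removed because its value (-0.42) had been seen before the list was made, so the outcome depends on this 1 gene.

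Clock genes were lower (per1b, nr1d2b, ciarta and cry-dash among them), and collection at a different time of day was weighed. It predicts higher levels of clock genes of the opposite phase by more than 0.2, whereas these averaged 0.0353 ± 0.0583 (SE over 6 genes). That SE treats the genes as independent, which they are not. Their own moderated SE ran from 0.0779 (nfil3) to 0.153 (clockb). The values therefore argue only weakly against a phase shift of that size and do not exclude it. A difference in light before collection was not tested. An effect of 6PPD on the clock genes was not tested apart from the comparison itself.

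With 3 libraries against 3 there are 10 ways to divide them, so a share under 0.05 cannot be reached. The real division gave the highest value in 1 of 10 for each of 3 counts. It called 522 genes against at most 0 in the others (limma, with 163 to 1273 genes at an unadjusted p under 0.05), 80 genes with at least a doubling or halving against at most 0, and 18 lists against at most 17. List calls under a preset correlation were therefore common without the real grouping, although the other divisions still hold part of the difference between groups. For nuclear oxidative phosphorylation genes and skeletal muscle genes, 3 and 4 of the 10 divisions placed the list as far from all genes as the real one. For cell cycle, inflammation, pigment cell and circadian clock genes only the real one did. The same held for lists with small changes, such as aryl hydrocarbon receptor targets, endothelial markers, angiogenic signalling and reference genes. It therefore does not set the former lists apart.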
